A study of Mus musculus with 2 samples.

How the data were processed

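RNA of gastrocnemius muscle was read as long reads in 2 libraries, which per the labels are biological replicates 1 and 2 of 1 group of female B6CASTF1/J mice aged 18 to 20 months, each started from 2 µg of RNA. The labels give the same donor record, with the same pair of identifiers, for both. They do not say how many animals each library came from. The p-values here therefore measure only the difference between these libraries, which may be technical in part. The submitters' labels give the assembly as mm10 and name ERCC and SIRV spike-in mixes. The deposited tables hold raw counts of reads per transcript model, with 1 table per library, and list only models with at least 1 read. The other deposited columns, per the file headers, are the number of exons and the length in bases of each model, and the deposited annotations give the 1-based position of each model on mm10. The models combine GENCODE M21 with models added in each library, named by TALON in the deposited annotations, and carry 1 of 7 classes: Known, incomplete splice match (ISM), annotated splice sites in an unannotated combination (NIC), at least 1 unannotated splice site (NNC), Genomic, Antisense and Intergenic. The aligner, the filter applied to the alignments and all versions are not given in the sources used here.

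The choices of gene lists, tests, filters and most alternatives were made before the data were examined. A gene count was the sum of all models of an annotated gene, and CPM was taken over reads of annotated endogenous genes. Genes with at least 10 reads over both libraries were tested. The count in replicate 1 was compared with its share expected from TMM effective library sizes (edgeR 4.0.16 in R 4.3.3; factors 1.04 and 0.961) by a 2-sided exact binomial test, with Benjamini-Hochberg adjustment over 8394 genes and a threshold of 0.05. This test compares 2 libraries and knows counting error only. Folds carry exact 95% intervals, and a count of 0 was bounded by the 3 reads it allows. As an alternative, the common dispersion of the 2 libraries (0.0617) was taken as given in an edgeR exact test; no quasi-likelihood fit was possible with 1 library per side.

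Preset gene lists were summed as CPM per library. The median log2 ratio of replicate 1 over replicate 2 of each list was ranked among 10000 random lists of equal size matched on expression, and, as an addition made after the data were seen, among lists matched on expression and annotated length. Shares of myosin heavy chains, of 8 fast and slow pairs and of transcript classes carry Wilson 95% intervals and were compared by Fisher's exact test with Benjamini-Hochberg adjustment within each family. The lists covered myosin heavy chains, fast and slow fibre proteins, sarcomere structure, glycolysis and glycogen, creatine and adenylate kinases, calcium handling, nuclear and mitochondrial respiratory genes, oxygen and fatty acid use, the neuromuscular junction, protein breakdown, ageing, imprinted and long non-coding RNA, sex-linked genes, immediate early genes, alternatively spliced genes, very long transcripts and 9 sets of markers of other cells. Text names the 20 most abundant genes, members of these lists, the 10 genes with the smallest p in each direction among those differing at least 2-fold, the leading isoform of each alternatively spliced gene, the 10 unannotated NIC or NNC chains with the highest lower CPM, and the 5 intergenic and 5 antisense loci with the most reads.

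Models of different libraries were matched by chromosome, strand and intron chain, since identifiers of added models need not be shared. Isoform shares were taken over Known, NIC and NNC reads for genes with at least 20 such reads in each library, and the share of the leading isoform was compared by Fisher's exact test with Benjamini-Hochberg adjustment over 3297 genes. Splice sites and coding parts were read from GENCODE M21. Inclusion of short exons was counted among reads whose model started before the exon and ended after it. It was taken for constitutive coding exons with at least 20 such spanning reads in each library. An exon counted as included only where the model held both of its boundaries exactly, so an exon with a shifted boundary counted as absent. Copies of Gapdh were single-exon genes sharing over 50% of their 21-base words with its annotated transcripts. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and DESeq2 1.42.0 for the alternative size factors, with seed 1.

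Reads of annotated endogenous genes numbered 1117891 in replicate 1 and 975696 in replicate 2, and the median detected gene held 10 and 9 of them, so that only large folds can be called for a typical gene. The procedures were tested on simulated counts with the depth of these libraries. The simulated gene counts held sampling noise only, without the further scatter seen between the libraries. They therefore do not measure how many calls in the real counts were false. Genes to be changed were drawn from those with at least 50 reads over both libraries, so their rates do not apply to a typical gene. Of 100 genes made 2-fold higher in replicate 1, 78 were called, and of 100 made 2-fold lower, 46, with 9 of 8184 unchanged genes called; the median log2 estimates were 0.97 and -0.97. For leading isoforms shifted by 20 percentage points, 113 of 200 were called, with 5 of 3097 unchanged genes. No SIRV reads were in the tables, so spike-in results rest on ERCC RNAs alone. Reads of the parental alleles, base-level errors and priming within A-rich sequence were not analysed here. Some members of the lists and 1 antisense locus are not reported here.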

Results

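The data were 2 long-read RNA libraries from gastrocnemius muscle of female B6CASTF1/J mice aged 18 to 20 months, labelled as biological replicates 1 and 2 of 1 group. No treatment, second age or second tissue was in the series, so levels were described in both libraries and the libraries were compared with each other, not with another condition. Replicate 1 held 1175829 reads on 80416 transcript models and replicate 2 held 1017384 reads on 74962. Annotated endogenous genes took 1117891 and 975696 of them. Reads fell on 13149 annotated genes in replicate 1 and 12699 in replicate 2, with 6842 and 6247 genes holding at least 10 reads. A gene with 0 reads could have been present at up to 2.68 counts per 1000000 reads (CPM) in replicate 1 and 3.07 in replicate 2. Levels are given as mean ± SD of CPM over the 2 libraries (n = 2); folds between libraries carry exact 95% intervals, which cover counting error only.

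The muscle was dominated by the contractile and energy genes of fast glycolytic fibres. Atp2a1, the calcium pump of the fast sarcoplasmic reticulum, was the most abundant gene at 171569 ± 28104 CPM, or 17.2 ± 2.81% of reads. It was followed by the muscle creatine kinase Ckm (58279 ± 4616), skeletal actin Acta1 (55480 ± 5506), the type IIb myosin heavy chain Myh4 (24786 ± 8197) and fast troponin C Tnnc2 (23321 ± 4679). The first 3 genes alone took 28.5 ± 1.80% of reads and the first 20 took 45.2 ± 1.10%. Other sarcomere genes among the 20 were Tpm1 (18205 ± 6203), the fast Z-disc protein Actn3 (13382 ± 193), Mybpc2 (8323 ± 290), the light chains Mylpf (8218 ± 2592) and Myl1 (7524 ± 1465), Tcap (5241 ± 79.9) and the type IIx myosin Myh1 (4311 ± 4174). The glycolytic enzymes Aldoa (13274 ± 4476), Ldha (7333 ± 205), Eno3 (7212 ± 316), Pkm (4237 ± 102) and Pfkm (3874 ± 492) were in the same set. The adenine nucleotide carrier Slc25a4 (8211 ± 82.7), adenylate kinase Ak1 (4979 ± 178) and carbonic anhydrase Car3 (3875 ± 502) made up the rest.

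The slow fibre programme was higher in replicate 2. The slow myosin Myh7 had 183 reads in replicate 1 and 2330 in replicate 2, a 15.8-fold difference (13.6 to 18.5). All 12 slow fibre genes with enough reads were higher in replicate 2, and the summed level of the list was 881 CPM in replicate 1 and 5748 in replicate 2. The list included slow troponins Tnnc1 (7.15-fold, 5.80 to 8.88), Tnnt1 (5.37-fold, 4.62 to 6.27) and Tnni1 (4.02-fold, 2.82 to 5.86). It also included the slow calcium pump Atp2a2 (6.97-fold, 5.49 to 8.94), the ventricular and slow light chains Myl2 (5.44-fold, 3.36 to 9.20) and Myl3 (3.74-fold, 2.86 to 4.93), and slow tropomyosin Tpm3 (5.06-fold, 4.22 to 6.11). The stretch-responsive Csrp3 (4.96-fold, 2.93 to 8.84) and Ankrd2 (2.18-fold, 1.46 to 3.28), the calcium store protein Casq2 (2.98-fold, 1.59 to 5.85) and the Z-disc gene Myoz2 (2.04-fold, 1.41 to 2.99) completed the 12. Fhl2 had 1 read in each library and was not tested. Of the 12, 6 stayed called when scatter between the libraries was added to counting error, as described below. The median log2 ratio of the list (replicate 1 over replicate 2) was -2.31, below all 10000 random lists of equal size matched on expression. The oxidative fast myosins moved the same way: Myh2 (type IIa) was 7.06-fold higher in replicate 2 (6.30 to 7.94) and Myh1 5.78-fold (5.47 to 6.12).

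**Figure D1:**
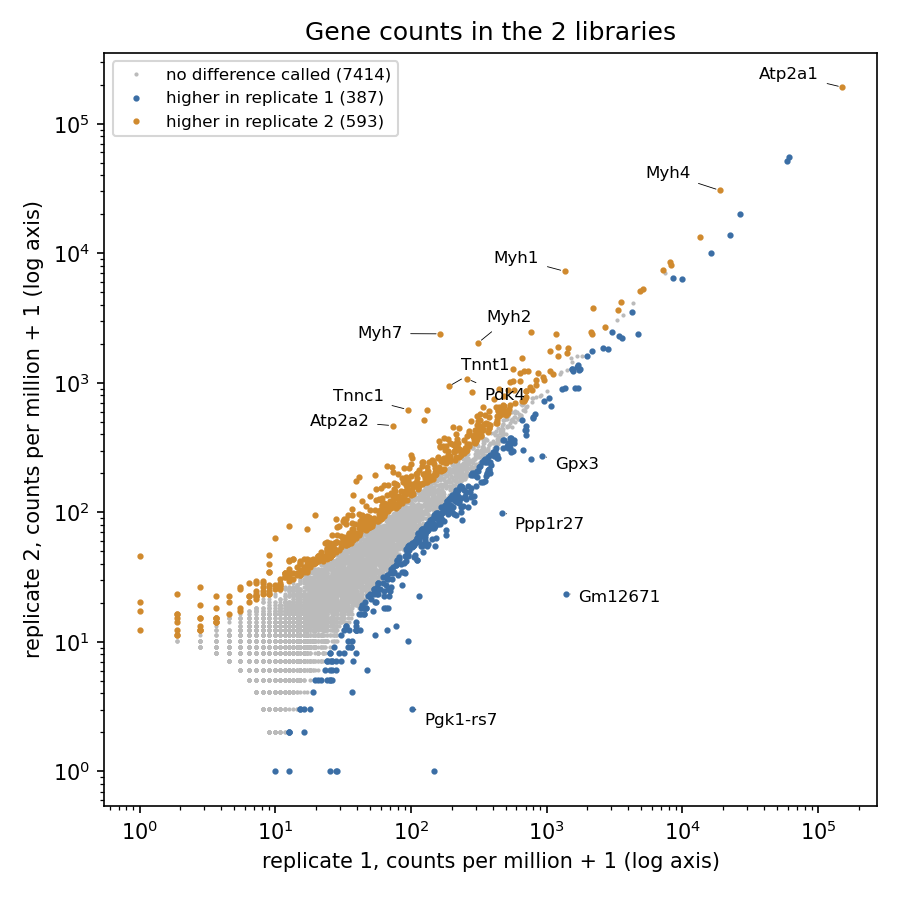
Each point is an annotated gene with at least 10 reads over both libraries, plotted by its CPM plus 1 in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis). Grey genes were not called different; 387 genes were called higher in replicate 1 and 593 in replicate 2, with Myh7, Myh2, Myh1 and Tnnc1 standing above the diagonal.

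Within each library, Myh4 was the main myosin heavy chain, but its share differed. It took 91.2% of myosin heavy chain reads in replicate 1 (95% interval 90.8 to 91.5) and 72.3% in replicate 2 (71.9 to 72.8). Myh1 rose from 6.53% (6.22 to 6.85) in replicate 1 to 17.2% (16.8 to 17.5) in replicate 2, Myh2 from 1.50% (1.35 to 1.66) to 4.82% (4.61 to 5.03) and Myh7 from 0.786% (0.680 to 0.908) to 5.65% (5.43 to 5.87). These shares rested on 23288 reads in replicate 1 and 41259 in replicate 2 and needed no scaling between libraries. They did depend on the transcript classes counted. With Known, NIC and NNC only, the mean of the libraries went from 11.9% to 20.8% for Myh1 and from 3.22% to 7.10% for Myh7. Part of this shift came from class names. In replicate 2, Myh4 held 7088 reads of these classes, or 16091 when a chain given such a class in either library was counted in both. The developmental myosins Myh3 (3 and 7 reads) and Myh8 (1 and 1) and the minor Myh7b (3 and 4) were near absent. The cardiac Myh6 had 0 reads in replicate 1 and 5 in replicate 2, and the extraocular Myh13 had none in either library, so each Myh13 share was at most 0.0129% and 0.00727% at the 3 reads that a 0 count allows. Fisher's exact test separated the libraries for Myh1, Myh2, Myh4 and Myh7 of the 9 genes compared; the largest adjusted p among these 4 (Benjamini-Hochberg) was 3.97e-118, for Myh2.

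All 8 fast and slow paralog pairs held a larger slow share in replicate 2. Tnnt1 took 6.75% of the reads of Tnnt3 and Tnnt1 in replicate 1 and 33.4% in replicate 2. Mybpc1 took 8.67% of the reads it shared with Mybpc2 in replicate 1 and 22.5% in replicate 2. Both pairs depended on the transcript classes counted. As a mean of the libraries, the Tnnt3 share went from 79.9% to 96.8% with Known, NIC and NNC only and 100% with Known only. The Mybpc2 share went from 84.4% to 83.5% and 94.9% with the same restrictions. Known, NIC and NNC reads of Tnnt1 numbered 23 in replicate 1 and 54 in replicate 2. The slow members of the other pairs stayed small but moved the same way: Tnni1 from 0.774% to 5.42%, Tnnc1 from 0.351% to 3.01%, Myl3 from 0.767% to 3.40%, Myl2 from 0.187% to 1.46%, Casq2 from 0.398% to 1.00% and Atp2a2 from 0.0477% to 0.243%. The weakest pair was Casq1 and Casq2, with an adjusted p of 0.00183 by Fisher's exact test (Benjamini-Hochberg over 8 pairs).

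**Figure D2:**
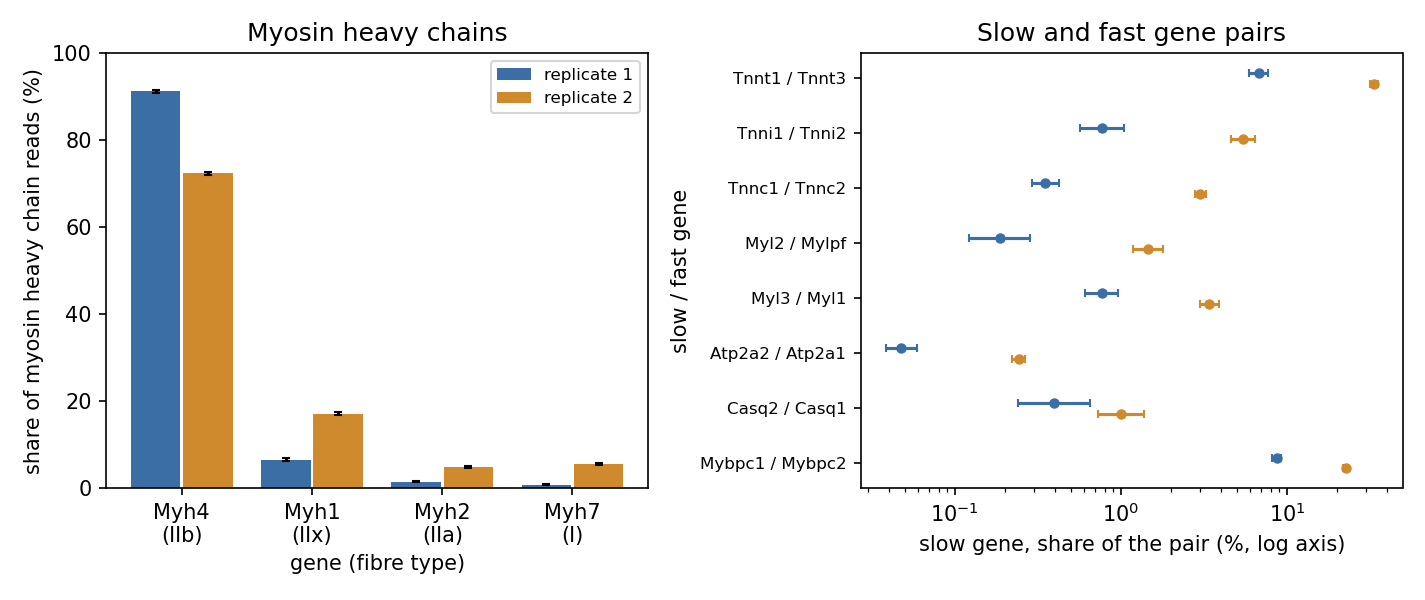
Left, the share of each of 4 myosin heavy chain genes among all myosin heavy chain reads (%), with the fibre type in brackets. Right, the share of the slow gene in each slow and fast pair (%, log axis); blue is replicate 1, orange is replicate 2, error bars are 95% intervals for counting error, and in every pair the slow share was larger in replicate 2, as for Tnnt1 at 6.75% and 33.4%.

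The fast fibre list, by contrast, split evenly: 7 of its 14 genes were higher in replicate 1 and 7 in replicate 2. Its summed level was 291594 ± 24542 CPM, or 29.2 ± 2.45% of reads. Higher in replicate 1 were the fast troponin I Tnni2 (1.83-fold, 1.74 to 1.92), Tpm1 (1.51-fold, 1.48 to 1.54), the regulatory light chain Mylpf (1.45-fold, 1.41 to 1.50), Tnnt3 (1.29-fold), parvalbumin Pvalb (1.28-fold), Tnnc2 (1.23-fold) and Myl1 (1.22-fold). Besides Myh1 and Myh2, Myh4 (1.74-fold, 1.71 to 1.77), Atp2a1 (1.37-fold, 1.36 to 1.38), Casq1 (1.17-fold), Mybpc2 (1.14-fold) and Actn3 (1.06-fold) were higher in replicate 2. The median log2 ratio of 0.10 stood at percentile 94.4 of lists matched on expression and 85.1 of lists matched on expression and annotated length. Of the 14, only Myh1 and Myh2 stayed called with the scatter added, and Actn3 changed direction with total counts. Leading isoforms of Tnnc2, Myl1, Tnnt3 and Tpm1 had 700 to 1208 nt, against 3485 nt for Atp2a1 and 3611 nt for Mybpc2. Ratios of all genes followed length, as given below, so fibre type and length cannot be told apart in this split.

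Sarcomere scaffold genes leaned toward replicate 2. Of 22 genes, 12 were higher in replicate 2, 3 were higher in replicate 1 and 7 were not called, at a summed 78566 ± 2662 CPM. Mybpc1, the slow thick filament regulator, was 3.49-fold higher in replicate 2 (3.23 to 3.78). The Z-disc actinin Actn2 was 2.52-fold higher there (2.31 to 2.76) and beta tropomyosin Tpm2 2.20-fold (2.05 to 2.35). The giant protein titin (Ttn, 1.97-fold) and the myofibril assembly gene Nrap (1.98-fold) followed. Higher in replicate 1 were Myoz1 (1.37-fold), Myot (1.13-fold) and Acta1 (1.06-fold). Desmin (Des, 3512 ± 221 CPM) and Ldb3 (208 ± 12.5) were not called. None of the 22 stayed called with the scatter added. The list median of -0.43 stood at percentile 0.320 of lists matched on expression and 1.26 of lists matched on expression and annotated length.

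Oxidative metabolism leaned toward replicate 2, by smaller folds. Pdk4, which restrains glucose oxidation, was 4.48-fold higher (3.93 to 5.12), and 10 of 14 oxygen and fatty acid genes were higher in replicate 2 with 4 not called. They included the fatty acid carrier Fabp3 (1.98-fold, 1.73 to 2.27), lipoprotein lipase Lpl (1.96-fold, 1.64 to 2.35), Ucp3 (1.93-fold) and myoglobin Mb (1.72-fold, 1.51 to 1.97). Of the 12 mitochondrially encoded genes tested, 7 were higher in replicate 2 and 5 were not called; mt-Co2 was 2.00-fold higher, mt-Nd4 1.96-fold and mt-Co1 1.81-fold (1.68 to 1.95). Nuclear respiratory genes were mixed: 10 of 22 were higher in replicate 2, among them Ndufs1 (1.66-fold), Cox7a1 (1.61-fold) and Uqcrc1 (1.43-fold), while Ndufa4 (1.40-fold) and Cox8b (1.39-fold) were higher in replicate 1. The median log2 ratios were -0.55 for oxygen and fatty acid genes (percentile 0.210), -0.55 for mitochondrial genes (percentile 0.230) and -0.14 for nuclear respiratory genes (percentile 27.3, or 0.810 with matching on length as well). When scatter between the libraries was added to counting error, Pdk4 alone of these 3 lists stayed called.

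Glycolysis and creatine genes showed no common direction. In the list of 19 glycolysis and glycogen genes, at 45879 ± 4556 CPM together, 5 of the 18 tested were higher in replicate 1, 7 were higher in replicate 2 and 6 were not called. Fbp2 (2.24-fold, 1.62 to 3.12), Pgk1 (1.56-fold), Aldoa (1.50-fold, 1.47 to 1.54), Tpi1 (1.18-fold) and Pgam2 (1.12-fold) were higher in replicate 1. The phosphorylase kinase subunit Phka1 (2.07-fold, 1.86 to 2.29), hexokinase Hk2 (1.99-fold) and glycogen synthase Gys1 (1.46-fold) were higher in replicate 2. The creatine and adenylate kinases summed to 64651 ± 4071 CPM. The mitochondrial Ckmt2 was 1.95-fold higher in replicate 2 (1.78 to 2.14) while Ckm differed by 1.03-fold. No gene of either list stayed called with the scatter added. Gapdh held only 53 and 43 reads (45.7 ± 2.36 CPM), and its value is uncertain because near-identical copies took most of the reads, as described with the pseudogenes.

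Calcium handling genes other than Atp2a1 were present at moderate levels. The ryanodine receptor Ryr1 stood at 1000 ± 71.7 CPM, the voltage sensor Cacna1s at 978 ± 359, Casq1 at 3502 ± 201, sarcalumenin Srl at 2989 ± 1135 and Hrc at 1335 ± 113. Of 20 tested genes, 8 were higher in replicate 2, led by Srl (1.88-fold) and Cacna1s (1.84-fold), and 3 were higher in replicate 1. These 3 were Pvalb, the calcium channel subunit Cacng1 (2.24-fold, 1.79 to 2.83) and Mrln (2.54-fold, 1.98 to 3.29), which encodes the pump inhibitor myoregulin. None of the 20 stayed called with the scatter added. The pump inhibitor sarcolipin, Sln, had 4 and 3 reads.

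Denervation and developmental genes were low. The junction list summed to 307 ± 76.5 CPM and only Chrna1 of 13 tested genes was called, 3.22-fold higher in replicate 1 (1.64 to 6.92); Chrng had 0 reads in both libraries, and Ncam1 and Runx1 had 3 and 6 reads in total. Among 15 protein breakdown genes, the ubiquitin ligase Fbxo32 (2.02-fold, 1.61 to 2.55), the lysosomal protease Ctsl (2.33-fold), Map1lc3a (1.70-fold) and Sqstm1 (1.52-fold) were higher in replicate 1. Foxo1 (2.36-fold) and the metallothionein Mt1 (2.78-fold) were among those higher in replicate 2. Trim63, the other main atrophy ligase, was 447 ± 15.9 CPM and was not called. Of the ageing genes, the cell cycle inhibitor Cdkn1a was 5.71-fold higher in replicate 1 (3.10 to 11.5). Trp53 (28 and 10 reads) and Sesn1 (78 and 60) were not called, and Cdkn2a, Gdf15, Fgf21, Lmnb1, Il6 and Sesn2 had no reads, so each was below the limits of 2.68 and 3.07 CPM.

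Imprinted and nuclear RNAs were sparse. H19 was the most abundant at 99.1 ± 5.34 CPM, followed by Neat1 at 84.4 ± 23.6. Malat1 had 41 and 6 reads, 5.51-fold higher in replicate 1 (2.33 to 15.9), and Xist had 13 and 1, 10.5-fold (1.57 to 445). Of the Y-linked genes, Ddx3y had 1 read, in replicate 2, and Eif2s3y, Kdm5d and Uty had none. Immediate early genes were low: Jun was 2.39-fold higher in replicate 1 (1.60 to 3.67), Zfp36 had 3 and 13 reads (5.38-fold higher in replicate 2, 1.48 to 29.4), and Fos had 1 read.

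Markers of other cells were present at low levels, with fibroblast genes the highest apart from genes shared with muscle. The fibroblast list summed to 2345 ± 174 CPM, most of it Gsn (1803 ± 263). The collagens were higher in replicate 2: Col1a2 5.24-fold (2.49 to 12.3), Col3a1 3.91-fold (2.91 to 5.32) and Col1a1 3.56-fold (2.32 to 5.58), whereas decorin, Dcn, was 1.71-fold higher in replicate 1. Rgs5, a pericyte gene, was 2.06-fold higher in replicate 2, and Pdgfrb had 3 and 14 reads (5.79-fold, 1.62 to 31.4). Replicate 1 held more of Lyz2 of macrophages (4.95-fold, 2.21 to 13.0), Mbp of Schwann cells (3.37-fold, 1.72 to 7.22) and the tendon regulator Scx (2.92-fold, 1.66 to 5.45). Macrophage genes (median 1.02, percentile 99.3), tenocyte genes (0.85, percentile 99.3) and globin and other erythroid genes (0.94, percentile 99.8) lay to the replicate 1 side of the lists matched on expression, less so with matching on length as well (percentiles 97.8, 99.0 and 97.5), and only Lyz2 and Scx of these 3 lists were called. Endothelial genes such as Cldn5 and Pecam1 summed to 172 ± 34.8 CPM with none of 10 called. Adipocyte genes other than Car3 were rare, with Adipoq at 6 reads in each library, and satellite cell genes were almost absent apart from Cdh15 (42.9 ± 12.8 CPM), with no read of Pax7.

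Of the 10 named genes higher in replicate 1, 2 were single-exon processed pseudogenes whose reads were uncertain. Gm12671, a processed copy of Gapdh, had 1552 reads in replicate 1 and 22 in replicate 2, and Pgk1-rs7, a copy of Pgk1, had 112 and 2 (45.1-fold, 12.2 to 377). In replicate 2, 867 reads lay in a model on the minus strand of chromosome 4 at 91851487 to 91851668 (mm10, 1-based) that shared 1 base with the 3' end of Gm12671 and was named as a separate locus. When 395 unannotated models that overlapped an annotated gene on its strand were joined to that gene, Gm12671 held 1552 and 889 reads and Pgk1-rs7 150 and 129. E030018B13Rik, annotated as coding, had 165 reads in replicate 1 and 0 in replicate 2 (at least 44.3-fold).

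Other genes higher in replicate 1 were annotated as coding. The secreted peroxidase Gpx3 was 3.17-fold higher (2.77 to 3.64), the phosphatase regulator Ppp1r27 4.42-fold (3.55 to 5.56), the mitochondrial translation regulator Mss51 2.78-fold (2.41 to 3.22) and the actinin partner Pdlim3 2.02-fold (1.76 to 2.32). Tmem100 was 9.49-fold higher (4.82 to 21.3) and Cfap77 4.91-fold (3.08 to 8.21). In all, 387 genes were called higher in replicate 1 and 593 higher in replicate 2 out of 8394 tested (exact binomial test, Benjamini-Hochberg adjusted p below 0.05), and 137 and 271 of these differed at least 2-fold. With scaling to total counts the direction of the set turned, with 586 of 1038 called genes (56.5%) higher in replicate 1 against 39.5% with TMM scaling, because the ratios shifted by 0.11 log2; none of the 20 named genes with the smallest p changed direction, but Actn3 and Slc25a4 did. When the scatter between the libraries was added to counting error, by an edgeR exact test with the common dispersion taken as given, 24 genes passed. That dispersion came from the same 2 libraries and so holds the difference itself; the test ranks genes against the scatter of all genes and is not independent support. Of the 16 on the replicate 2 side, 6 were slow fibre genes (Myh7, Tnnc1, Atp2a2, Tnnt1, Tpm3, Myl2), and others were Myh1, Myh2, Pdk4, the stress gene Gadd45g, Arrdc2 and Smtnl1. The 8 on the replicate 1 side included Gm12671, with the smallest p, and Pgk1-rs7, whose folds fell to 1.41 and 0.937 when overlapping loci were joined, as well as E030018B13Rik, Ppp1r27 and Tmem100. Gadd45g, Arrdc2 and Smtnl1 were outside the naming rule and were chosen after their values were seen.

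Over all tested genes, log2 CPM correlated at Pearson 0.916 and Spearman 0.899 over 8394 genes, which are not independent replicates. The common biological coefficient of variation was 24.8%, and the gene counts varied 8.26 times as much as sampling alone would give (chi-square per degree of freedom). ERCC spike-in RNAs varied 1.10 times as much, but this ratio grows with reads per RNA, so the 2 values are not a like comparison. By the same estimator, over RNAs with at least 100 reads, the dispersion was 0.0575 for 2375 genes and 0.00203 for 15 spikes. The ERCC RNAs took 2.57% of reads in replicate 1 (30211 reads on 52 spikes) and 0.748% in replicate 2 (7609 reads on 44), a 3.44-fold difference in share. Gene ratios also followed annotated length: the median log2 ratio was 0.36 for genes under 1000 nt and -0.36 for genes of 6000 nt or more. The Spearman correlation of ratio and length was -0.340 across genes, with a permutation p of 1e-04, the smallest possible.

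Transcript models followed the annotation for most reads. Complete annotated models (Known) took 62.1% of endogenous reads in replicate 1 and 57.3% in replicate 2, and those with an unannotated splice site (NNC) took 17.5% and 20.8%. A single Atp2a1 chain, described below, held 79.7% and 84.5% of the NNC reads; the other NNC reads were 3.54% of reads in replicate 1 and 3.21% in replicate 2. Partial chains (ISM) took 11.0% and 10.7%, annotated sites in an unannotated combination (NIC) 3.93% and 5.21%, genomic models 3.18% and 2.70%, antisense models 1.89% and 2.89% and intergenic models 0.428% and 0.419%. Much of the antisense difference lay at 1 locus on chromosome 17, described below. It held 4025 and 10258 reads, against 21661 and 29132 reads of all antisense models. That locus also overlapped annotated genes on its own strand, so its class does not establish antisense transcription. All classes but the intergenic one (adjusted p 0.279, Fisher's exact test, Benjamini-Hochberg over 7 classes) differed between the libraries under the deposited class names. With classes rebuilt from intron chains, the direction turned for partial chains (7.60% in replicate 1 and 7.96% in replicate 2) and for unannotated combinations of annotated sites (4.82% and 4.40%). Counted as models rather than reads, ISM was the largest class at 26.9 ± 0.452%, with Known at 19.6 ± 0.0612% and NNC at 19.2 ± 0.862%. Most models were rare: 60.3% in replicate 1 and 61.1% in replicate 2 rested on 1 read.

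**Figure D3:**
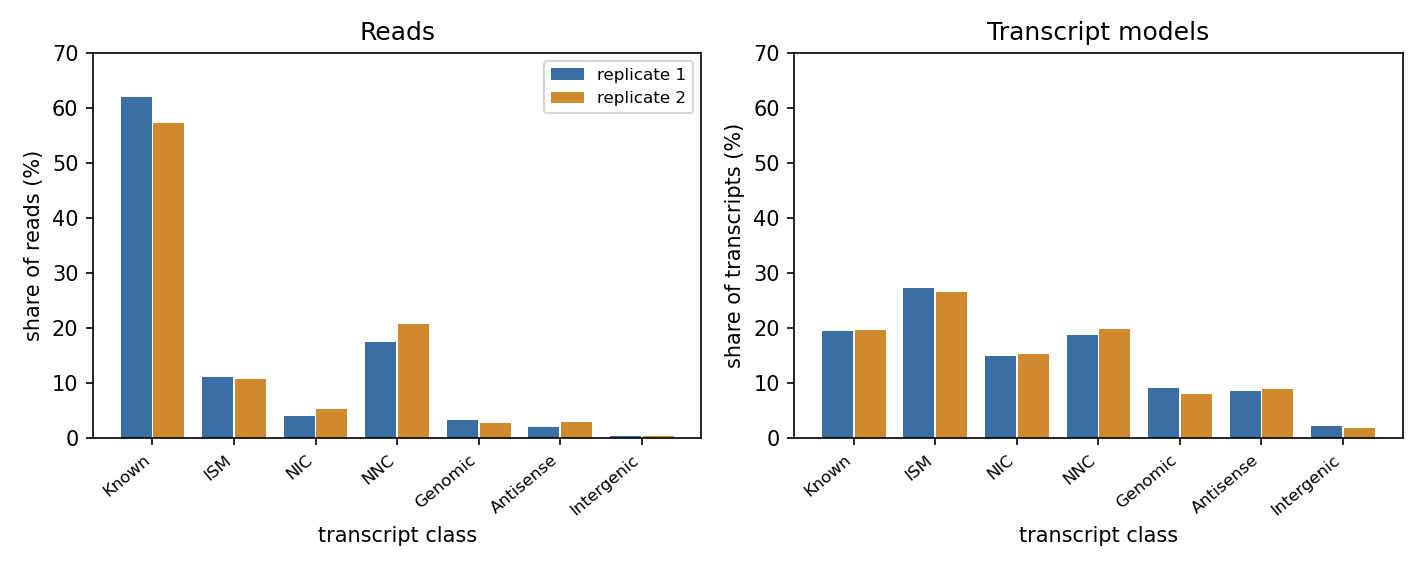
Share of reads (left, %) and of transcript models (right, %) in each of 7 transcript classes, for replicate 1 (blue) and replicate 2 (orange). Known models held 62.1% and 57.3% of reads but 19.6% of models, while partial ISM models were the most numerous.

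Of the unannotated multi-exon models (ISM, NIC and NNC), 35.4 ± 1.19% had the same intron chain among the models of the other library, against 80.9 ± 3.23% of Known models. The share was 42.4 ± 2.43% for ISM, 39.0 ± 1.11% for NIC and 23.7 ± 0.194% for NNC. The repeated structures carried most reads, 89.9% of unannotated reads in replicate 1 and 90.8% in replicate 2. The single Atp2a1 chain held 159541 and 177540 of these reads, so the repeated share of the other structures was lower. Among 16357 unannotated chains found in both libraries, 1378 (8.42%) carried a different class name in each. Near-annotated sites were common: 37.9% of unannotated-site structures in 1 library and 32.0% of those in both lay within 10 bp of an annotated site.

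Most muscle genes with known alternative splicing were led by the same isoform in both libraries. Of 36 such genes, 34 had at least 20 full-chain reads in each library, and over both libraries 22 were led by an annotated isoform and 12 by an unannotated chain. In 6 of the 34 the libraries had different leads: Mybpc1, Rcan1, Tnnt3, Fxr1, Cd36 and Mef2d. Of these, only Mybpc1 and Tnnt3 differed in the share of the leading isoform by the test given below, so the other changes of lead may be counting error. In Mef2d the 2 leads held 8 and 4 reads in replicate 1 and 5 and 6 in replicate 2. The alpha tropomyosin isoform Tpm1-205 held 98.6% and 98.4% of Tpm1 reads in replicates 1 and 2, Tpm2-202 held 94.1% and 95.0%, and the pyruvate kinase isoform Pkm-202 held 96.6% and 96.5%. Mybpc2-201 (96.5% and 96.3%), Cacng1-201 (98.8% and 98.9%), Rtn4-201 (98.9% and 100%), Slc25a3-206 (93.6% and 93.7%), Fhl1-204 (92.3% and 94.1%) and Myom1-203 (92.0% and 90.1%) were similar. Myl1 was divided, with the shorter Myl1-202 at 75.2% and 75.5%, as were Jsrp1-203 (77.1% and 71.6%), Asph-206 (65.3% and 75%), Clcn1-201 (84.6% and 80%), Camk2b-202 (49.4% and 61.0%), Nfix-201 (52.8% and 54.3%), Tmod4-201 (45.9% and 52.4%) and Nfe2l1-211 (41.5% and 39.2%). Pdlim3-203 held 93.7% and 86.0%. Ldb3 and Ppargc1a had too few full-chain reads.

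Over both libraries, unannotated chains led Atp2a1, Tnnt3, Tnnt1, Bin1, Pdlim5, Pdlim7, Mef2c, Trdn, Mbnl1, Mbnl2, Cd36 and Fxr1. The membrane-shaping gene Bin1 was led by a 14-exon chain with 2 unannotated introns at 71.3% and 66.0%. This chain matched the part annotated as coding in Bin1-203, which does not by itself show what protein it makes. The splicing regulator Mbnl2 was led by a 7-exon chain at 73.2% and 79.3%. Trdn was the most divided, with its leading 37-exon chain at 12.7% and 13.2%, and Mbnl1, Mef2c and Pdlim7 were led at 32.2% and 25%, 27.5% and 25.8%, and 22.7% and 17.4%. The Pdlim5 chain held 90.3% and 89.3%. The chains of Fxr1 (41.4% and 47.6%) and Cd36 (25% and 28.8%) led in replicate 2 only. In replicate 1 the annotated Fxr1-201 (49.3%) and Cd36-204 (30.8%) led, and neither chain differed in share by the test given below. In Tnnt3 a different unannotated chain led in each library, by 421 against 389 reads in replicate 1 and 227 against 210 in replicate 2. The leading chains of Cd36 (13 and 15 reads), Tnnt1 (7 and 26, or 30.4% and 48.1%) and Pdlim7 (10 and 4) rested on few reads.

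Over 3297 genes, the share of the leading isoform differed between the libraries in 16 (Fisher's exact test, Benjamini-Hochberg adjusted p below 0.05). The count depended on the reads used, with 90 genes when ISM reads were added to the denominator and 5 with Known reads only, and in simulation 56.5% of shifts of 20 percentage points were called. Of the 3297 genes, 8.28% were led by an unannotated chain; the leading isoform held a median 88.5% of reads. On the muscle list, 4 genes passed this correction and 6 when adjusted over the list alone. Mybpc1-202 fell from 45.3% in replicate 1 to 18.3% in replicate 2 (adjusted p 2.44e-42), where an unannotated 32-exon chain led with 556 of 2168 reads. Tpm3-205 rose from 79.9% to 92.4% (adjusted p 0.0103) and the leading Tnnt3 chain fell from 28.4% to 19.7% (adjusted p 1.79e-04), both by Fisher's exact test. The kinase Sgk1-201 fell from 96.2% to 70%, Dctn1-201 from 56.2% to 39.5% and Gpam-201 from 72.5% to 35.6%; these 3 were named after their values were seen. The calcineurin regulator Rcan1 was led by Rcan1-202 in replicate 1 (66.3%) and by Rcan1-201 in replicate 2 (57.5%), at an adjusted p of 0.0554 by Fisher's exact test. The differences with the smallest p, in Aldoa and Myh4, came in large part from the class names: with identical intron chains merged whatever their class, the leading chain held 93.1% and 90.6% of Aldoa reads and 63.7% and 55.9% of Myh4 reads, smaller differences that still passed (adjusted p 1.40e-09 and 6.10e-32, Fisher's exact test). Of the 16 genes, Tfeb and Tmem65 no longer differed after this merging (adjusted p 1 for both); both were named after their values were seen.

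The leading Atp2a1 chain was unannotated and held 98.3% of full-chain reads in replicate 1 and 98.0% in replicate 2 (159541 and 177540 reads). It had 22 exons against 23 in the annotated full-length transcript, which had 0 reads in both libraries. On the minus strand of chromosome 7 (mm10, 1-based), 1 intron from 126462188 to 126462778 replaced 2 annotated introns, so the annotated 18-nt exon at 126462500 to 126462517 was missing and the exon before it was 26 nt longer. Other constitutive coding exons of 20 nt or less were also often not found at their exact boundaries. Of 24 such exons, 18 were in under 10% of spanning reads, and the median was 0% against 99.3% for exons of 21 to 30 nt. They included exons of 7 nt in Tnni2 (0 of 4425 and 0 of 1962 spanning reads), 14 nt in Tnnt3 and Tnnt1, 4 nt in Tnni1 and 18 nt in Ryr1. The 18-nt exon of Atp2a2 was retained in 71 of 72 and 365 of 392 reads, and that of Trdn in 265 of 267 and 423 of 424.

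**Figure D4:**
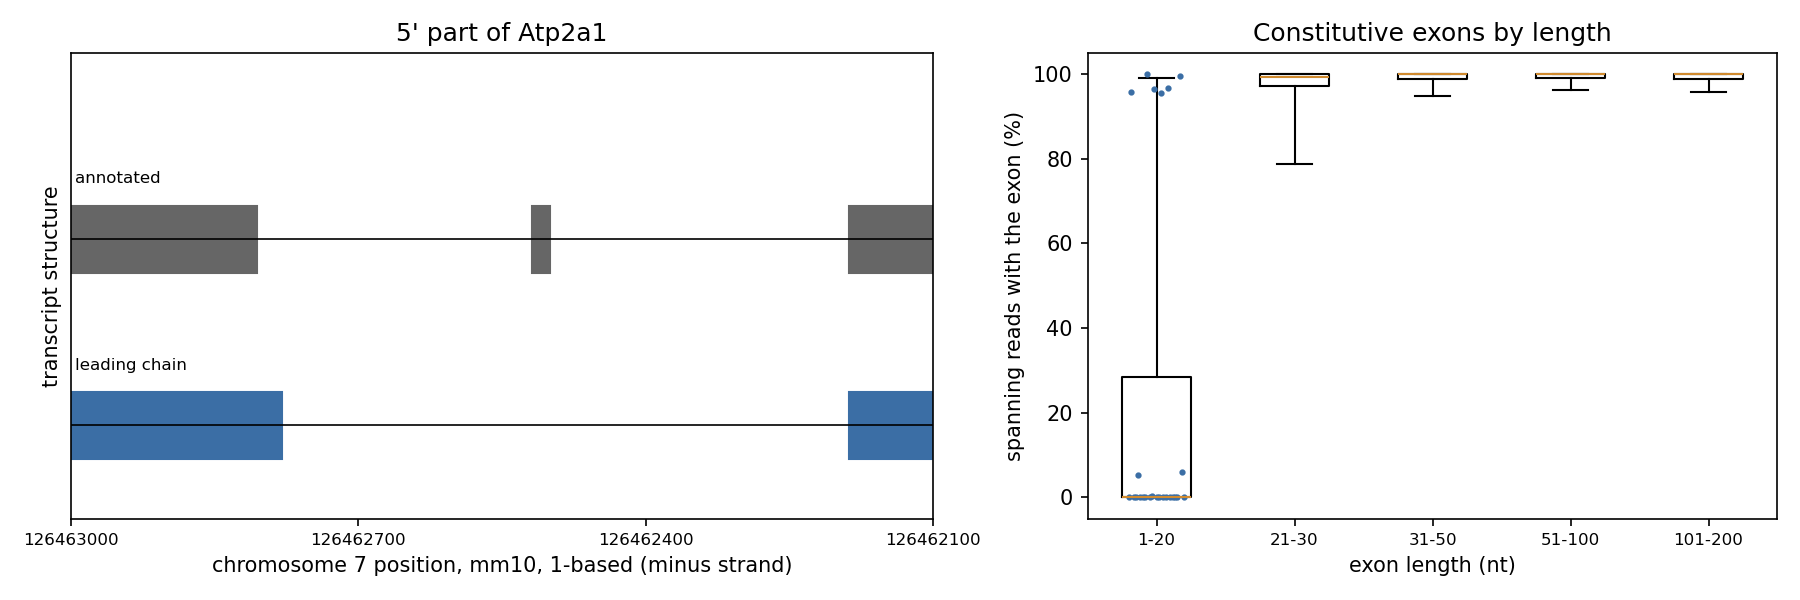
Left, the 5' part of the annotated Atp2a1 transcript and of its leading chain along chromosome 7 (position in bases, mm10), with boxes for exons; the 18-nt exon is absent from the leading chain. Right, the share of spanning reads that contain an exon at its exact boundaries (%) by exon length (nt). Boxes show quartiles, whiskers percentiles 5 and 95, and points each exon of 20 nt or less (Atp2a1 among the points but not in the box).

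In all, 7863 unannotated NIC or NNC chains were found in both libraries, in 3464 genes, and 599 of them reached 10 CPM in both. After Atp2a1, the most abundant was a 7-exon Tnni2 chain (2010 ± 1038 CPM), which joined annotated sites from 142442499 to 142443170 on chromosome 7 without the 7-nt exon. Next were Srl (6 exons, 1359 ± 479), Ndrg2 (16 exons, 1202 ± 57.5, with an annotated coding part) and Oaz1 (5 exons, 1160 ± 67.6). A further Atp2a1 chain (546 ± 146), Vdac3 (465 ± 20.2), Tmed2 (456 ± 25.1), Bin1 (421 ± 126) and Mknk2 (390 ± 35.4) completed the 10. Leaving Atp2a1 aside, 49.9% of NIC and NNC reads in replicate 1 and 51.3% in replicate 2 kept an annotated coding part. Such a match does not by itself show that a full-length protein is made.

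Among loci classed as antisense or intergenic, the one with the most reads was opposite Gm26917 and Gm42418 on the minus strand of chromosome 17 from 39843013 to 39848035, with 4025 and 10258 reads; it also overlapped the annotated AY036118 and CT010467.1 on its own strand. Next came a single-exon locus opposite Klhl31 on chromosome 9 (77656524 to 77660127; 2033 and 3231 reads), where Klhl31 itself had 129 and 128 reads. Smaller antisense loci lay opposite 2900097C17Rik (190 and 223) and Cdv3 (199 and 201). Over the 20 most abundant genes, antisense reads were 0.0268% of sense and antisense reads in replicate 1 and 0.0212% in replicate 2; over the spike-in RNAs they were 0.853% and 0.963%. Of the intergenic loci, 1 on chromosome 11 (20334833 to 20335012; 764 and 273 reads) and the chromosome 4 locus beside Gm12671 touched Gapdh copies. The others were on chromosome 7 from 28187294 (120 and 125), on chromosome 4 from 133095968 (84 and 103) and on chromosome Y from 67834528 (250 and 119).

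Very long transcripts were seen mostly in part. Of the reads of Ttn, 28.9% in replicate 1 and 27.0% in replicate 2 were in full-chain classes, and the longest titin model had 16707 nt against 106824 nt in the annotation. Neb reached 22311 nt of 22489 nt in replicate 1. Ryr1 was 94.3% and 95.6% partial, and Flnc 84.9% and 89.1%. The 6-kb myosins varied: the full-chain classes held 63.6% and 67.6% of Myh1 reads and 68.3% and 81.8% of Myh7 reads, but 34.7% and 39.3% of Myh2 reads and 46.9% and 23.8% of Myh4 reads. The low Myh4 share in replicate 2 came from the class names, since it was 53.9% when a chain given a full-chain class in either library was counted in both. Dystrophin (Dmd) had 15 and 16 reads, Syne1 had 8 and 2, and Nebl had none.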

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

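The values here come from reads outside annotated genes, which the gene comparisons did not use. In these libraries of female mice, 364 reads in replicate 1 and 194 reads in replicate 2 lay on intergenic models of chromosome Y, above the 3 reads that a count of 0 allows. The largest was a 2-exon model on the minus strand from 67834528 to 67839300 (mm10, 1-based), with 250 reads in replicate 1. Of the annotated Y-linked genes on the preset list, Ddx3y had 0 reads in replicate 1 and 1 in replicate 2, and Eif2s3y, Kdm5d and Uty had 0 in both. The annotated Y-linked gene with the most reads was a Gapdh copy, Gapdh-ps15, with 17 and 13. No biological explanation was tested, and copies of these sequences elsewhere in the genome were not searched.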

How the results depend on the processing

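Removal of the length trend, joining of overlapping loci, rebuilt classes and lists matched on length were chosen after the result was seen. Apart from the class names of Myh4 and Aldoa given below, the cause of each change was not tested. Of the genes that differed, the count of 980 became 24 with the common dispersion in an edgeR exact test, all 24 among the 980; other settings gave 664 (adjusted p below 0.01) to 1038 (total counts, 839 shared), with 776 after the length trend was removed (644 shared) and 979 after loci were joined (972 shared). The Pearson correlation of 0.916 moved to 0.926 with no filter, 0.912 with at least 50 counts, 0.909 with Known, NIC and NNC only, and 0.901 and 0.945 with pseudocounts of 0.1 and 10 CPM. The coefficient of variation of 24.8% moved to 25.5% without genomic models and 26.0% with Known, NIC and NNC only. Restriction to Known, NIC and NNC moved the Myh1 share to 20.8% and the Myh7 share to 7.10%, sarcomere genes to 83059 CPM and glycolysis genes to 36443 CPM. Class names account for part of the myosin and glycolysis shifts. With identical chains merged, reads of these classes went from 7088 to 16091 for Myh4 in replicate 2 and from 1148 to 16747 for Aldoa in replicate 1. Restriction to Known moved Myh4 to 60.2%, Myh1 to 27.8% and Myh7 to 8.05%. Known, ISM and NIC shares became 63.8%, 9.21% and 3.55% with at least 5 reads per model; ISM became 10.05% with at least 2 reads and 7.78% with classes rebuilt from intron chains, where the difference between the libraries turned for ISM and NIC. Unannotated chains found in both libraries became 72.6% with at least 2 reads, 96.5% with at least 5, 46.1% with sites up to 10 bp apart and 30.6% with 3' ends within 100 bp. The 16 genes with different isoform shares became 90 with ISM reads added, 5 with Known only, 25 with at least 50 reads and 14 with identical chains merged. Without either library, the slow fibre list ranged from 881 to 5748 CPM, Myh7 from 0.786 to 5.65% and Myh4 from 72.3 to 91.2%. With total counts, 56.5% of the called genes were higher in replicate 1 against 39.5%, so the balance between the libraries turned, and Actn3 and Slc25a4 changed direction. With Known only, the Atp2a1 share of the reads of Atp2a1 and Atp2a2 went from 99.9% to 0%. The quasi-likelihood test was not run. No paired analysis was possible because there was 1 group.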

Other observations

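Tests of short slow fibre genes, of Atp2a1 coding length and of Gapdh copies were chosen after the result was seen; the others were written before it. These muscles read as fast glycolytic tissue, with Atp2a1 alone at 17.2% of reads and Myh4 as the main myosin in both libraries. Against that shared background, replicate 2 carried more reads, beyond counting error, of the slow myosin and its troponins, light chains, tropomyosin and calcium pump, the type IIa and IIx myosins, Pdk4, and several genes of fatty acid use and mitochondria. Of these, only 6 slow fibre genes, Myh1, Myh2 and Pdk4 stood out from the scatter of all genes between the same libraries, which ranks genes and is not independent support. Myh7 rose from 0.786% to 5.65% of myosin reads while the share of Myh4 fell from 91.2% to 72.3%, although the level of Myh4 itself was 1.74-fold higher in replicate 2. By counting error alone, collagens were higher in replicate 2, and Cdkn1a, Fbxo32, Lyz2 and Scx in replicate 1; none of these stood out from that scatter.

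The first pattern is the set of 980 genes that differed between the libraries. Length bias of library preparation could account for part of it: 65.7% of the called genes (62.7 to 68.6) stayed called after a linear length trend was removed. It is argued against for slow fibre genes, since the 5 members under 2000 nt had a median log2 ratio of -2.42, outside the 95% range of -0.22 to 0.72 of lists matched on expression and length. Scatter of preparation cannot be told apart from a difference between the tissues: the spike-in dispersion was 0.00203 (-0.00484 to 0.0108) against 0.0575 for genes, but the spikes were 505 to 1124 nt long and each side had 1 library. A larger content of slow fibres in the tissue stays open as a hypothesis. Of 4 further slow genes, 2 were lower in replicate 1 after scaling (Pln 6 and 5 reads, Myom3 6 and 19). The other 2 were not (Smpx 193 and 106, Myl6b 1 and 0), and all but Smpx had few reads. Smpx was called higher in replicate 1 by counting error (log2 ratio 0.55), the direction opposite to the hypothesis. With total counts Pln also turned, by less than its counting error.

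The second pattern is the leading Atp2a1 chain without the annotated 18-nt exon. A splice form with these sites that makes the annotated protein is argued against. Its coding length on the genome changed by 8 nt, which is not a multiple of 3. Missed alignment of short exons could explain the loss of this exon. The comparison was with constitutive exons of over 100 and up to 200 nt. Median inclusion of 24 other exons of 20 nt or less was 100 percentage points lower (94.7 to 100). The 26 nt added to the exon before it exceed a missed exon of 18 nt by the same 8 nt. These are lengths on the genome. Base sequences were not examined, so placement of the bases of the missed exon there was not tested. Exceptions such as the 18-nt exons of Atp2a2 and Trdn, which were retained, show that length alone did not decide it. Unannotated chains of Tnni2, Tnnt3 and Tnnt1 also lacked short exons, that of Tnni2 with annotated splice sites only. No biological explanation of those was tested.

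The third pattern is the small number of reads on Gapdh, 53 and 43, in a tissue rich in glycolytic mRNA. Placement of Gapdh reads on processed copies likely accounts for it: 18 of 57 single-exon copies had reads, and they held 98.0% of the reads of Gapdh and its copies as a mean of the libraries, 3697 against 53 in replicate 1 and 1660 against 43 in replicate 2. Taken with its copies, Gapdh reached 3355 CPM in replicate 1 and 1745 CPM in replicate 2, or 4113 and 2915 CPM with overlapping unannotated loci joined to the copies. The same reads bear on the call of Gm12671, which shares 100% of its 21-base words with Gapdh. Transcription of some copies stays open, and no biological explanation was tested.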
